A study of Mus musculus with 16 samples.

How the data were processed

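Total liver RNA of 16 male C57BL/6 mice was hybridised to expression arrays, 1 array per mouse. The labels sort the mice into 4 groups of 4 by genotype, wild type (WT) or CYP7A1 transgenic (Tg), and by diet, standard chow or a Western diet. Per the labels, mice aged 12 to 14 weeks ate their diet for 4 months, and the Western diet drew 42% of its calories from fat and held 0.2% cholesterol. Livers were taken after a fast of about 16 h, and 250 ng of RNA was labelled with biotin by an Illumina amplification kit. The animals are separate mice, so the spread between arrays includes the spread between animals.

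The authors deposited 1 scanner file for each array with a signal intensity for each of 25697 rows, on a linear scale. These intensities carried no detection p-values, control probes or slide names, and no value lay near 0, so no background had been subtracted. Per array, the mean signal ran from 348.1 to 446.6 and the median from 70.3 to 86.6. The authors also deposited values of the same arrays in log2 units, whose scaling step is not given in the sources used here. Set against the scanner files it kept the order of signals within every array, with 0 breaks. It lay within 0.074 of the quantile-normalized log2 scanner signals (median difference 0.0018). Its column medians ran from 6.254 to 6.264. It is therefore log2 and not centred per gene, and it served as an alternative source. Of the 25697 rows, 12508 shared their value on all 16 arrays with at least 1 other row, leaving 18138 distinct rows.

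From the scanner signals, the background was corrected by normexp with an offset of 50, arrays were quantile-normalized, and log2 was taken, with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8). The control-based correction (neqc) foreseen as first choice needs control probes or detection p-values and could not be run, so the stated fallback was used. Rows in the upper 50% by mean over all 16 arrays were kept (log2 mean above 6.29, 12846 rows, 12052 of them named). Gene symbols came from the platform annotation given with the series. It named 23978 rows with 1 symbol each, 0 rows with several and left 1719 rows unnamed, for 16593 symbols. Of the named rows, 23962 matched a gene by Entrez identifier in a RefSeq table of assembly GRCm38.p6, which served for names only. The files name no genome build, so no coordinates are given. A gene with several rows was read by the row of highest mean, and 21 shared values that carried 2 symbols (42 symbols in all) were left out, which left 7788 genes. Some genes kept by this filter have a group mean under 6.29, near background, and a fold against such a mean is a lower bound. The offset of 50 also shrinks folds from means above 6.29, most where signals are low. Probe sequences were not used here, so signals of near-identical families (the Gsta, Mup, Serpina1, Cyp2a, Cyp4a, lysozyme and hemoglobin genes) can include related transcripts.

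All comparisons came from 1 limma fit (lmFit, contrasts, eBayes) with a mean for each of the 4 groups and 12 residual degrees of freedom. Tg was compared with WT on each diet, Western diet with chow in each genotype, and the genotype effects on the 2 diets with each other (the interaction). P-values are two-sided and adjusted by Benjamini-Hochberg over the 7788 genes, and a gene was called at an adjusted p under 0.05 with no minimum fold. Errors of log2 fold changes are limma's standard errors (SE), and those of levels are standard deviations (SD) over 4 arrays. The main design, the processing alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. Lists were drawn from general knowledge of liver biology and cover metabolism, stress and immune responses and markers of the cell types a liver sample can hold. Each of the 29 lists with at least 3 tested members was tested by limma's camera with a preset correlation of 0.01, adjusted over all 145 list and comparison pairs. Members called were counted over all genes and also adjusted over the list alone. Adipocyte markers (0 tested members), pancreatic acinar markers (2) and muscle markers (1) had too few members on the array above the filter.

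The genes named are Cyp7a1 and, per comparison of groups, the 10 largest increases and 10 largest decreases among called genes whose 4 arrays of one group all lay above the 4 of the other. For the interaction they are the 10 genes of smallest adjusted p. Symbols that are only clone or predicted-locus names are counted and not named. Up to 4 called members of largest change are named per list, any member for bile acid and cholesterol synthesis, and the brightest markers of other cell types. Other names were chosen after their values were seen and serve only where a short count is spelled out.

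The procedure was tested on data simulated for the 7788 genes with 200 of them changed. In the 4 comparisons of groups it recovered 94% to 98% of 2-fold changes and 84% to 94% of 1.5-fold changes. In the interaction it recovered 98% and 60%, and no comparison made more than 15 false calls. Fewer genes were changed than any comparison of the real arrays called, so that number of false calls does not carry over to them. Of 140 unchanged lists 0 were called, and 5 of 5 shifted lists were. The simulated genes varied independently of each other, so this cannot show how often lists of correlated genes are called falsely. The number of arrays limits the precision of every value. Alternatives changed the background correction, the scaling, the source of values, the filter, the row per gene, the variance model, array weights, the arrays in the fit, thresholds, and the arrays left out. A stricter filter on mean signal, a merge of rows with shared values and a term for a split in the lowest signals were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.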

Results

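Liver mRNA was measured in 16 mice, 4 in each combination of genotype label (WT or Tg, a CYP7A1 transgene) and diet (chow or Western diet). Over the raw signals of all 25697 rows, Spearman correlations were 0.931 to 0.953 for arrays of the same group (24 pairs). For arrays of different groups they were 0.918 to 0.942 (96 pairs). The first 3 principal components of the normalized signals of the 7788 tested genes held 37.3%, 21.5% and 11.1% of the variance. The 5th percentile of raw signal averaged 58.3 on the 8 arrays of replicates 1 and 2 and 53.6 on the 8 of replicates 3 and 4, with 2 arrays of each group on either side. The split was uneven between groups, widest in WT_Chow (62.9 and 61.8 against 53.4 and 54.3) and overlapping in WT_WD (55 and 56.6 against 55.5 and 52.3). With this split as a term, chosen after the data were seen, the counts of called genes were 816 and 1258 for genotype on chow and Western diet, 1560 and 854 for diet in WT and Tg, and 458 for the interaction. Cyp7a1 differed between genotypes by -4.82 and -4.42 on the log2 scale within replicates 1 and 2 and within replicates 3 and 4 on chow, 2 arrays against 2 each. On the Western diet these differences were -4.79 and -4.42.

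The first question was the level of the targeted gene itself. Cyp7a1 encodes cholesterol 7-alpha-hydroxylase, the rate-limiting enzyme of classical bile acid synthesis, and 1 probe row reads it on this array. Its signal was lower, not higher, in the Tg-labelled livers. The mean log2 signal was 11.69 ± 0.42 (SD, n = 4) in WT-labelled and 7.07 ± 0.63 in Tg-labelled livers on chow. On the Western diet it was 11.21 ± 1.02 and 6.60 ± 0.52 (SD, n = 4 each). The fall was 24.6-fold on chow (log2 fold change -4.62, SE 0.42, limma adjusted p = 1.636e-06) and 24.4-fold on the Western diet (-4.61, adjusted p = 1.079e-06). All 8 WT-labelled arrays (10.022 to 12.409) lay above all 8 Tg-labelled arrays (6.238 to 7.852). Diet made no difference that passed the test, with -0.48 in WT (adjusted p = 0.4579) and -0.47 in Tg (adjusted p = 0.5228), and the interaction was 0.02 with SE 0.59 (adjusted p = 0.9919). On the Western diet Tg replicates 2 and 3 (6.282 and 6.238) lay under the signal filter of 6.29, near background. The fold on that diet, the diet effect in Tg and the interaction are therefore uncertain in size. The probe sequence and the species of the transgene are not given in the sources used here, so every direction between genotypes below rests on the labels.

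**Figure D1:**
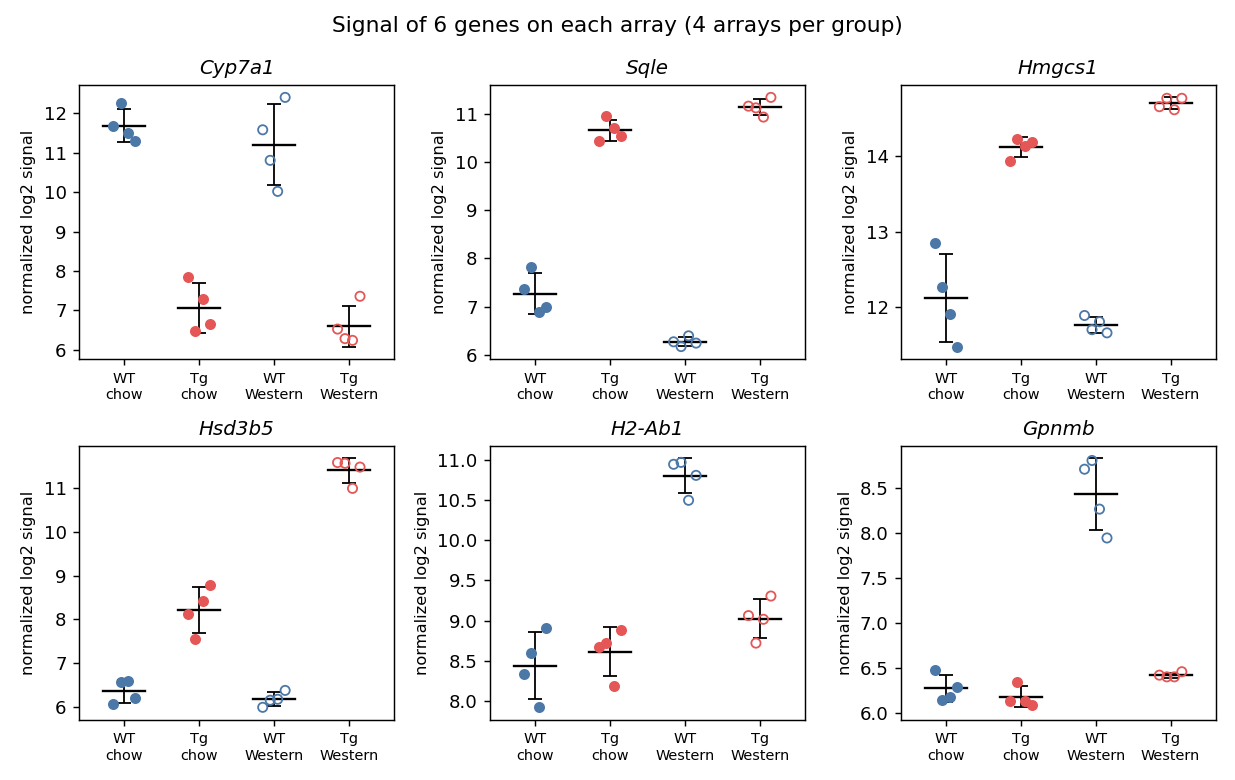
Normalized log2 signal of Cyp7a1, Sqle, Hmgcs1, Hsd3b5, H2-Ab1 and Gpnmb on each of the 16 arrays (vertical axes; horizontal axis, the 4 groups), with blue for WT, red for Tg, filled dots for chow and open dots for Western diet; lines are group means and bars are ± SD of 4 arrays. Cyp7a1 lay between 10.022 and 12.409 on the WT arrays and between 6.238 and 7.852 on the Tg arrays, and H2-Ab1 and Gpnmb stood highest in WT livers on the Western diet.

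The comparison of genotypes on chow asks how livers labelled transgenic differ in the absence of a dietary load. In Tg-labelled livers the enzymes of cholesterol synthesis were higher nearly throughout the pathway. Sqle, which makes squalene epoxide, rose 10.5-fold (log2 fold change 3.39, SE 0.16, n = 4 against 4, limma adjusted p = 1.148e-09). Fdps, which makes farnesyl diphosphate, rose 8.56-fold (SE 0.18 on the log2 scale), and the lanosterol demethylase Cyp51 rose 7.43-fold (SE 0.15). Msmo1, Lss, Idi1, Nsdhl, Mvd and Hmgcs1, enzymes from the first step after acetoacetyl-CoA to the late sterol intermediates, rose 6.66, 4.84, 4.78, 4.29, 4.28 and 3.97-fold (SE 0.10 to 0.21). Some genes of glutathione conjugation and drug metabolism were lower, among them the glutathione transferases Gsta1 (9.02-fold lower, log2 fold change -3.17, SE 0.39) and Gsta2 (7.81-fold lower, SE 0.32) and the cytochrome Cyp2a5 (5.29-fold lower, SE 0.32).

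Of 15 tested cholesterol synthesis genes 13 rose and 0 fell (14 rose when adjusted over the list alone), with a median rise of 4.28-fold (camera adjusted p = 3.655e-34). Of 7 other targets and regulators of SREBP2, the sterol-sensing transcription factor, 6 rose, led by Rdh11 (log2 fold change 1.40), the sterol carrier Stard4 (1.40) and Insig1 (1.21), a brake on SREBP processing (camera adjusted p = 1.989e-08). These 2 lists kept their calls with an estimated correlation, at adjusted p = 0.003088 and adjusted p = 0.01883. Of 32 xenobiotic genes 16 fell and 0 rose, including Gstm2 at -1.82 (20 fell and 1 rose when adjusted over the list alone; camera adjusted p = 5.287e-11; adjusted p = 0.05658 with an estimated correlation). Of 20 male-biased liver genes 10 rose (13 when adjusted over the list alone; camera adjusted p = 7.695e-09; adjusted p = 0.1213 with an estimated correlation). They include the steroid reductase Hsd3b5 (3.63-fold higher, SE 0.20), the urinary protein Mup21 (log2 fold change 1.29) and the oxysterol hydroxylase Cyp7b1 (1.20, SE 0.23).

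Of 16 lipid droplet and steatosis genes 7 fell and 2 rose (camera adjusted p = 0.007564; adjusted p = 0.2829 with an estimated correlation). Without 1 array the median of this list ran from -0.37 to -0.11. Its mean difference was -0.76 within replicates 1 and 2 and -0.29 within replicates 3 and 4. The droplet proteins Cidea (7.38-fold lower, SE 0.55), Plin4 (log2 fold change -1.84) and Fitm1 (-1.62) and the acyltransferase Mogat1 (-1.33) fell, while the lipase Pnpla2 rose by 0.52. Of 23 macrophage markers 6 rose and 0 fell (12 rose when adjusted over the list alone), with a median of 0.52 and the chemokine Ccl6 at 0.58, a lower bound since its WT mean of 6.12 lies under the signal filter of 6.29 (camera adjusted p = 5.708e-06; adjusted p = 0.3594 with an estimated correlation). Tg_Chow replicate 4 stood apart on this list, with a mean of 0.91 above WT on chow against 0.40 to 0.45 on the other 3 arrays. Inflammatory cytokines (median 0.26, but 0.05 with no filter on signal, camera adjusted p = 0.01528, adjusted p = 0.3616 with an estimated correlation) and endothelial markers (median 0.16, and 0.00 to 0.22 without 1 array, with list means of 0.36 within replicates 1 and 2 and 0.05 within replicates 3 and 4, camera adjusted p = 0.04098, adjusted p = 0.6857 with an estimated correlation) passed weakly, with 2 members higher in each (4 and 2 when adjusted over the list alone). Both lost the call without WT_Chow replicate 1, and the endothelial list also without Tg_Chow replicate 2 or Tg_Chow replicate 3.

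Bile acid synthesis as a list did not pass (16 genes, camera adjusted p = 0.2183). Besides Cyp7a1, Cyp7b1 rose, and Cyp39a1 (0.42), Hsd3b7 (-0.39) and Acox2 (-0.36) passed in the full fit but not without Tg_Chow replicate 2 or with the other 8 arrays left out. Further large decreases were Hamp2, a hepcidin gene (7.67-fold, SE 0.49), the carbonic anhydrase Car3 (7.66-fold, SE 0.22), the galectin Lgals1 (6.78-fold, SE 0.20), the transcription factor Olig1 (4.48-fold, SE 0.20) and the kinase Aatk (4.27-fold, SE 0.37). Among genes of fat synthesis the desaturase Scd1 was -1.11 and the acyl-CoA synthetase Acsl3 was 0.97, both past the test, and the intestinal and hepatic apolipoprotein Apoa4 rose by 1.56. The Scd1 and Apoa4 lists did not pass as lists (fatty acid synthesis, camera adjusted p = 0.2425; lipoproteins, camera adjusted p = 0.6735). Across 7788 genes, 775 (10%) were called, 354 higher and 421 lower, with 42 and 44 at 2-fold or more, and in 1053 genes (13.5%, against 2.86% by chance) the 4 arrays of one group all lay above the other 4. The count fell to 418 without WT_Chow replicate 3, to 511 without Tg_Chow replicate 4 and to 316 with only these 8 arrays in the fit, and median scaling in place of quantile gave 185 higher and 1002 lower.

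The comparison of genotypes on the Western diet asks how livers labelled transgenic differ under a dietary load of fat and cholesterol. Tg-labelled livers again had higher cholesterol synthesis genes, by larger folds than on chow. Sqle was 29.4-fold higher (log2 fold change 4.88, SE 0.16, n = 4 against 4, limma adjusted p = 2.841e-12), Fdps 25.9-fold (SE 0.18), Msmo1 21.8-fold (SE 0.17) and Cyp51 21.7-fold (SE 0.15). Lss, Mvd, Idi1, Hsd17b7 and Hmgcs1 were 11.3, 10.2, 9.79, 8.64 and 7.60-fold higher. Hsd3b5, the male-biased steroid reductase, was at least 37.5-fold higher (SE 0.20, adjusted p = 7.571e-12). The WT means of Hsd3b5 (6.18), Sqle (6.27) and Mvd (6.12) and the Tg mean of Cidea (6.18) lie under the signal filter of 6.29, so the folds of these genes are lower bounds. Many, but not all, genes of lipid storage, antigen presentation and matrix were lower, among them Cidea (9.20-fold, SE 0.55), Plin4 (6.45-fold, SE 0.24) and lipoprotein lipase Lpl (4.81-fold, SE 0.27).

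All 15 cholesterol synthesis genes rose, with a median of 8.64-fold (camera adjusted p = 1.896e-42, adjusted p = 0.002089 with an estimated correlation). Of 7 other SREBP2 genes 6 rose (7 when adjusted over the list alone), with Stard4 at 2.87, Rdh11 at 2.63, Insig1 at 1.85 and Srebf2, which encodes SREBP2 itself, at 1.05 (camera adjusted p = 4.267e-12, adjusted p = 0.005891 with an estimated correlation). Fatty acid and triglyceride synthesis genes rose more modestly, 10 of 25 higher and 1 lower (median 0.20, and 0.12 to 0.27 without 1 array; camera adjusted p = 0.0003045; adjusted p = 0.2123 with an estimated correlation). WT_WD replicate 3 stood apart on this list, at -0.043 relative to WT on chow against 0.0529 to 0.0644 on the other 3 arrays, and without it the median was 0.14. The acetoacetyl-CoA synthetase Aacs (1.76), the elongase Elovl3 (1.62), the citrate lyase Acly (1.25) and the acetyl-CoA synthetase Acss2 (1.20) rose, and Srebf1 fell by 0.51. Of 20 male-biased genes 15 rose (16 when adjusted over the list alone), with C8b at 2.45, Serpina1e at 2.33 and Cyp4a12b at 2.17 (camera adjusted p = 3.306e-14, adjusted p = 0.05658 with an estimated correlation).

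All 6 tested genes of MHC class II presentation fell, with a median of 3.00-fold. H2-Ab1 was -1.78, the invariant chain Cd74 -1.62, H2-Aa -1.59 and H2-Eb1 -1.59 (camera adjusted p = 2.244e-11, adjusted p = 0.05809 with an estimated correlation). Of 25 stellate cell and matrix genes 20 fell and 0 rose (22 when adjusted over the list alone), with a median of 1.60-fold. They include the matrix protein Sparc (-0.90), the collagen Col4a1 (-0.88), the lysyl oxidase Loxl1 (-0.86) and the protease inhibitor Timp1 (-0.83), with camera adjusted p = 1.137e-15 and adjusted p = 0.05658 with an estimated correlation. Macrophage markers were divided, 10 of 23 lower and 3 higher (14 and 3 when adjusted over the list alone; median -0.71, but -0.42 with no filter on signal; camera adjusted p = 1.209e-06; adjusted p = 0.3442 with an estimated correlation). Gpnmb (4.04-fold lower, SE 0.14), the elastase Mmp12 (-1.96) and the galectin Lgals3 (-1.81) fell, while Cd163, Timd4 and Marco, markers of resident liver macrophages, rose by 1.14, 0.70 and 1.44. The resident markers Clec4f (-0.06, adjusted p = 0.856) and Vsig4 (-0.42, adjusted p = 0.4149) were not called. The call for Marco was lost without WT_WD replicate 2, Tg_WD replicate 1 or Tg_WD replicate 2.

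Lipid droplet genes fell in 9 of 16 cases and rose in 1, Plin2 at 0.53 (median -0.77, but -0.29 with no filter on signal, camera adjusted p = 5.304e-07, adjusted p = 0.05742 with an estimated correlation). Xenobiotic genes fell in 14 of 32 (16 lower and 1 higher when adjusted over the list alone; camera adjusted p = 8.633e-07; adjusted p = 0.1005 with an estimated correlation), with Gsta1 8.46-fold, Gsta2 6.70-fold and Cyp2a5 4.29-fold lower. Of 19 NRF2 and oxidative stress genes 5 fell (7 when adjusted over the list alone), including the metallothionein Mt1 at -1.25 and the peroxidase Gpx4 at -0.53 (camera adjusted p = 0.002719; adjusted p = 0.1099 with an estimated correlation; lost with median scaling). Of 21 genes of the unfolded protein response 7 rose and 1 fell (9 and 1 when adjusted over the list alone), with the chaperones Pdia6 at 0.67 and Hyou1 at 0.59 (camera adjusted p = 0.02452, adjusted p = 0.5816 with an estimated correlation). Interferon genes (8 higher and 3 lower of 23, or 10 and 3 when adjusted over the list alone, Igtp at 0.64; camera adjusted p = 0.03758; adjusted p = 0.6266 with an estimated correlation) and inflammatory cytokines (1 higher and 5 lower of 14, or 2 and 6 when adjusted over the list alone, Ccl4 at -0.78; camera adjusted p = 0.04317; adjusted p = 0.4504 with an estimated correlation) passed narrowly. The unfolded protein, interferon and cytokine calls were each lost without WT_WD replicate 1 or without Tg_WD replicate 4. Within replicates 1 and 2 and within replicates 3 and 4, the mean difference was 0.34 and 0.04 for the interferon list and 0.07 and 0.22 for the unfolded protein list. The unfolded protein call was also lost without WT_WD replicate 4 or Tg_WD replicate 3, the interferon call without WT_WD replicate 2 or Tg_WD replicate 2, and the cytokine call without WT_Chow replicate 2, WT_WD replicate 2 or Tg_WD replicate 3.

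Among bile acid genes, Cyp7b1 rose by 1.73 and the sterol 12-alpha-hydroxylase Cyp8b1 fell by 1.20 (SE 0.30, limma adjusted p = 0.01041), with Acox2 at -0.60. The list did not pass (camera adjusted p = 0.264). Slc10a1, the bile acid uptake transporter, rose by 0.91, and the gluconeogenic enzyme Pck1 by 1.27. Lgals1 (7.93-fold, SE 0.20) and the annexin Anxa2 (4.99-fold, SE 0.27) fell. In all, 1171 genes (15%) were called, 507 higher and 664 lower, with 59 and 78 at 2-fold or more, and 1797 (23.1%) had groups that did not overlap. Median scaling gave 338 higher and 972 lower. The genotype effects on the 2 diets had 276 called genes in common in the same direction, 117 higher and 159 lower, against 58.9 for independent lists. A further 20 were called in opposite directions, against 57.6. Across genes, which are not independent replicates, the fold changes on the 2 diets correlated at 0.54 (Pearson) and 0.31 (Spearman).

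**Figure D2:**
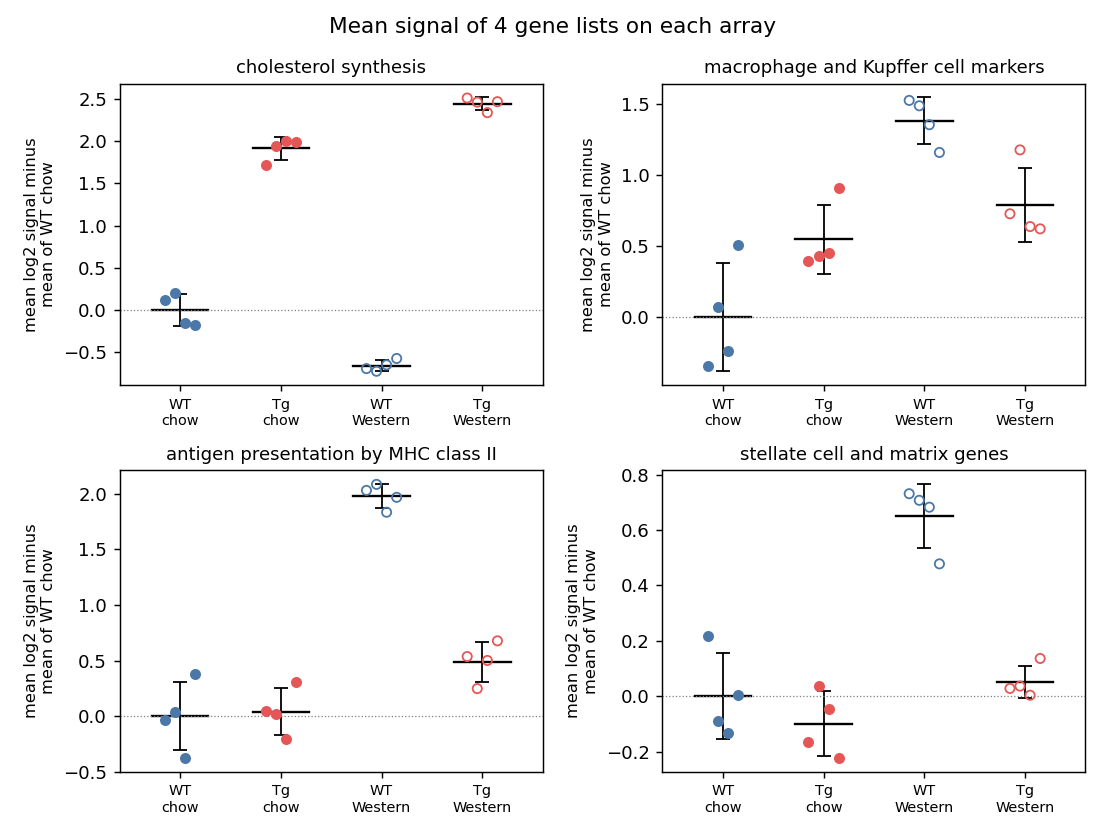
Mean log2 signal of 4 gene lists on each array minus the mean of WT on chow (vertical axes; horizontal axis, the 4 groups), with blue for WT, red for Tg, filled dots for chow and open dots for Western diet; lines are group means and bars are ± SD of 4 arrays. Cholesterol synthesis separates the genotypes on both diets, while MHC class II genes and stellate cell and matrix genes stand apart in WT livers on the Western diet.

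The comparison of diets in WT-labelled livers gives the response to the Western diet in mice labelled as carrying no transgene. Most tested macrophage and matrix genes and all tested MHC class II genes rose. Lpl, the lipoprotein lipase, rose 8.46-fold (log2 fold change 3.08, SE 0.27, n = 4 against 4, limma adjusted p = 1.026e-06). The macrophage genes Lgals3 (6.28-fold, SE 0.23), Lyz2 (6.09-fold, SE 0.44), Mmp12 (5.94-fold, SE 0.19) and Lyz1 (4.83-fold, SE 0.33) rose. So did the lipocalin Lcn2, a member of the acute phase list (6.04-fold, SE 0.51), the ubiquitin-like modifier Ubd (5.00-fold) and the transcription factor Fos (4.99-fold). Among the genes that fell were the male-biased serpin Serpina1e (12.2-fold, SE 0.37), the phospholyase Etnppl (3.73-fold), Nnmt, which methylates nicotinamide (3.60-fold), and Csad, an enzyme of taurine synthesis (3.05-fold).

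Of 23 macrophage and Kupffer cell markers 20 rose and 1, Cd163, fell, with a median of 3.08-fold (camera adjusted p = 2.453e-18, adjusted p = 0.0792 with an estimated correlation). All 6 MHC class II genes rose, with a median of 4.15-fold, H2-Ab1 at 5.17-fold, Cd74 at 5.07-fold, H2-Eb1 at 2.11 on the log2 scale and H2-Aa at 1.99 (camera adjusted p = 2.975e-13, adjusted p = 0.05658 with an estimated correlation). Of 25 stellate cell and matrix genes 23 rose (24 when adjusted over the list alone), among them the proteoglycan Lum (1.12), Timp1 (1.05, a lower bound since its mean of 6.17 on chow lies under the filter), the gelatinase Mmp2 (1.00) and Sparc (0.95), with camera adjusted p = 1.074e-16 and adjusted p = 0.05658 with an estimated correlation. Of 14 inflammatory cytokines 10 rose and 1 fell (11 and 1 when adjusted over the list alone), with Cxcl1 at 1.72, Il1b at 1.47 and Ccl4 at 1.24 (camera adjusted p = 2.838e-07, adjusted p = 0.06444 with an estimated correlation). Of 23 interferon genes 12 rose (15 when adjusted over the list alone), with Oasl2 at 0.99 and Ifit2 at 0.81 (camera adjusted p = 3.216e-07, adjusted p = 0.2123 with an estimated correlation).

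Markers of other cell types also changed in the same livers. Of 19 endothelial markers 10 rose (11 when adjusted over the list alone; median 0.34, and 0.22 to 0.43 without 1 array; camera adjusted p = 2.147e-05; adjusted p = 0.3519 with an estimated correlation), with Stab2 at 0.69. Of 5 lymphocyte and neutrophil markers 2 rose (3 when adjusted over the list alone), with Ccl5 at 1.19 and list means of 0.75 within replicates 1 and 2 and 0.26 within replicates 3 and 4 (camera adjusted p = 0.01403; adjusted p = 0.2561 with an estimated correlation; lost with no filter on signal). Of 5 erythroid and blood markers 4 fell and 1 rose, with the hemoglobins Hbb-bt (3.65-fold lower) and Hba-a1 (3.20-fold lower) at the front (camera adjusted p = 0.01136, adjusted p = 0.2655 with an estimated correlation). Hepatocyte markers had a median of -0.24 and did not pass as a list (6 of 21 lower, camera adjusted p = 0.1084). Without 1 array their median ran from -0.28 to -0.10, and the list passed under fry, with median scaling, with no filter on signal and without WT_Chow replicate 2. Of 24 acute phase genes 6 rose (7 when adjusted over the list alone), with Orm2 at 1.53 and Cd14 at 1.19 (camera adjusted p = 0.002198; adjusted p = 0.4504 with an estimated correlation; lost with median scaling). On this list WT_WD replicate 4 stood apart at 0.1351 against 0.4597 to 0.4925 on the other 3 arrays.

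Of 15 cholesterol synthesis genes 10 fell (12 when adjusted over the list alone), with Msmo1 at -1.32, Tm7sf2 at -1.29, Cyp51 at -1.14 and Hsd17b7 at -1.08 (median -0.55, camera adjusted p = 2.897e-08, adjusted p = 0.09661 with an estimated correlation). Of 7 other SREBP2 genes 4 fell, with Stard4 at -0.82 (camera adjusted p = 0.03274; adjusted p = 0.2952 with an estimated correlation; lost without WT_Chow replicate 1 or WT_WD replicate 4). Bile acid and sterol transporters rose in 6 of 14 genes and fell in 1 (7 and 2 when adjusted over the list alone), led by the sterol exporters Abcg5 (1.22) and Abcg8 (0.93) and the bile salt export pump Abcb11 (0.64), with camera adjusted p = 0.01085 and adjusted p = 0.2182 with an estimated correlation. Of 32 genes of fatty acid oxidation and PPARA targets 13 fell (15 when adjusted over the list alone), with Cyp4a14 at -1.27, Acot1 at -1.18 and Angptl4 at -0.94 (camera adjusted p = 0.000102, adjusted p = 0.3594 with an estimated correlation). Of 20 male-biased genes 7 fell and 2 rose, with C8b 3.01-fold and Elovl3 2.93-fold lower (camera adjusted p = 0.01371; adjusted p = 0.5209 with an estimated correlation; lost without WT_WD replicate 1).

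Bile acid synthesis did not pass as a list (camera adjusted p = 0.8707). Cyp2c70, which hydroxylates bile acids to muricholic acids, rose by 2.23 and Acot8 fell by 0.51. Cyp8b1 was -1.11, a call lost without WT_WD replicate 2. Pck1 fell 2.94-fold and the prostaglandin transporter Slco2a1 3.01-fold. In all, 1463 genes (18.8%) were called, 833 higher and 630 lower, with 111 and 31 at 2-fold or more, and 1702 (21.9%) had groups that did not overlap.

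The comparison of diets in Tg-labelled livers asks how mice labelled as carrying the transgene responded to the same diet. Hsd3b5 rose 9.10-fold (log2 fold change 3.19, SE 0.20, n = 4 against 4, limma adjusted p = 1.889e-07), Car3 6.27-fold (SE 0.22), Serpina7, the thyroxine-binding globulin, 5.84-fold (SE 0.31) and Hamp2 5.11-fold (SE 0.49). The cell cycle regulator Ccnd1 rose 3.83-fold, the proteoglycan Gpc1 3.08-fold, the protease inhibitor Spink1 2.99-fold, the transcription factor Nfe2 2.93-fold and the corticosteroid-binding globulin Serpina6 2.73-fold. Csad fell 5.03-fold (SE 0.28), the droplet protein Cidec 3.61-fold, the translation repressor Eif4ebp3 3.39-fold, the peroxisomal enzyme Ehhadh 3.10-fold, the urea cycle enzyme Asl 3.03-fold, Mt1 2.80-fold and the arrestin-related Arrdc4 2.76-fold. Hbb-bt (3.70-fold), Serpina1e (3.63-fold) and Etnppl (2.76-fold) also fell, and these 3 and Csad fell in WT too. Cxcl1 rose 2.82-fold, a call lost without Tg_Chow replicate 1 or Tg_WD replicate 4.

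Interferon response genes were the leading list, with 18 of 23 higher and 0 lower (23 higher when adjusted over the list alone). Ifit3 was 1.28, Cxcl9 1.25, Ifi47 1.13 and Isg15 1.10 (camera adjusted p = 1.168e-21, adjusted p = 0.03571 with an estimated correlation). Cholesterol synthesis rose in 6 of 15 genes (13 when adjusted over the list alone), with Mvd at 1.00, Sc5d at 1.00 and Dhcr7 at 0.68 (median 0.49, camera adjusted p = 3e-10, adjusted p = 0.05809 with an estimated correlation). Of the other SREBP2 genes 2 of 7 rose (4 when adjusted over the list alone), Rdh11 at 0.73 among them (camera adjusted p = 0.007564, adjusted p = 0.1965 with an estimated correlation). Fatty acid synthesis rose in 9 of 25 genes and fell in 1 (12 and 2 when adjusted over the list alone), with Aacs at 1.29, Scd1 at 1.02 and Fads2 at 0.89 (camera adjusted p = 6.217e-05, adjusted p = 0.1558 with an estimated correlation). Fatty acid oxidation fell in 11 of 32 (15 when adjusted over the list alone), with Cyp4a31 at -1.20 and Cyp4a14 at -0.77 (camera adjusted p = 8.633e-07, adjusted p = 0.2655 with an estimated correlation). Tg_WD replicate 3 stood apart on this list, at 0.1082 against -0.2778 to -0.241 on the other 3 arrays. Transporters rose in 5 of 14 genes (6 higher and 2 lower when adjusted over the list alone), with Abcb11 at 1.14, Abcg8 at 1.02 and Abcg5 at 0.75 (camera adjusted p = 0.003312, adjusted p = 0.1558 with an estimated correlation). On this list Tg_Chow replicate 4 stood apart at -0.1678 against 0.0615 to 0.0856 on the other 3 arrays.

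MHC class II genes rose in 3 of 6 cases (6 when adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.001068, adjusted p = 0.3442 with an estimated correlation). Of 23 macrophage markers 1 rose (median 0.24, and 0.14 to 0.37 without 1 array, camera adjusted p = 0.009298, adjusted p = 0.6266 with an estimated correlation), and the mean of this list was 0.54 higher on the Western diet within replicates 1 and 2 and -0.05 within replicates 3 and 4. For acute phase genes the same means were 0.55 and 0.00, and for the respiratory chain -0.05 and -0.17. Of 25 stellate cell and matrix genes 1 rose (camera adjusted p = 0.01403, adjusted p = 0.554 with an estimated correlation). Acute phase genes (3 of 24 higher, Saa4 at 0.87; camera adjusted p = 0.01202; adjusted p = 0.554 with an estimated correlation) and erythroid markers (2 of 5 lower, or 3 when adjusted over the list alone, Hba-a1 at -1.44; camera adjusted p = 0.006256; adjusted p = 0.2182 with an estimated correlation) also passed. So did cell cycle genes (2 of 9 higher, Ccnd1 and Mcm4, or 5 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.02325; adjusted p = 0.3519 with an estimated correlation) and the respiratory chain (3 of 38 lower, Ndufs4 at -0.39; camera adjusted p = 0.002105; adjusted p = 0.383 with an estimated correlation). Among these, the macrophage and acute phase calls were lost without Tg_WD replicate 2, the acute phase call also with median scaling, the matrix call without Tg_Chow replicate 4 or Tg_WD replicate 4, the respiratory call without Tg_Chow replicate 4 and the cell cycle call without Tg_Chow replicate 3.

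Among bile acid synthesis genes Cyp8b1 fell by 1.45 and Cyp2c70 rose by 1.27, with no call for the list (camera adjusted p = 0.8727). In all, 758 genes (9.7%) were called, 395 higher and 363 lower, with 37 and 19 at 2-fold or more, and 1327 (17%) had groups that did not overlap. The count fell to 481, 477 and 462 without Tg_WD replicate 1, 2 and 4. Of the genes called for diet, 273 were called in both genotypes in the same direction, 133 higher and 140 lower, against 71.6 for independent lists, and 19 in opposite directions, against 70.8.

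The interaction tests whether the genotype effect differed between diets. Hsd3b5 gave the clearest difference, a genotype effect larger on the Western diet by 3.37 on the log2 scale (SE 0.29, limma adjusted p = 1.626e-05, n = 4 per group). The sterol enzymes Tm7sf2 (1.68, SE 0.17), Hsd17b7 (1.33, SE 0.17) and Pmvk (0.95, SE 0.12), the retinol and sterol-regulated reductase Rdh11 (1.23, SE 0.16) and the plasma prekallikrein Klkb1 (0.90, SE 0.12) had positive terms. The myeloid genes Gpnmb (-1.92, SE 0.20), Trem2 (-1.53, SE 0.19) and Clec7a (-1.32, SE 0.16) and the polyamine acetyltransferase Sat1 (-1.08, SE 0.12) had negative ones. The terms of Hsd3b5 and Gpnmb use group means under the signal filter, so their size is uncertain. The cholesterol synthesis list had 13 positive and 0 negative calls among 15 genes (15 positive when adjusted over the list alone; median 1.22; camera adjusted p = 2.312e-22; adjusted p = 0.01058 with an estimated correlation).

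Macrophage markers had 16 negative and 1 positive of 23 (19 and 1 when adjusted over the list alone), with Lyz2 at -2.69 and Lgals3 at -2.01 (camera adjusted p = 2.555e-15, adjusted p = 0.1099 with an estimated correlation). All 6 MHC class II genes were negative, H2-Ab1 at -1.96 (camera adjusted p = 1.19e-12, adjusted p = 0.05658 with an estimated correlation). Of 25 stellate cell and matrix genes 9 were negative (18 when adjusted over the list alone), Sparc at -0.79 (camera adjusted p = 2.35e-11, adjusted p = 0.09661 with an estimated correlation). Inflammatory cytokines (5 of 14 negative, or 8 negative and 1 positive when adjusted over the list alone, Cxcl16 at -0.88; camera adjusted p = 5.43e-05; adjusted p = 0.1424 with an estimated correlation), lipid droplet genes (3 of 16 negative, Lpl at -2.77 and Cidec at -2.15; camera adjusted p = 0.01023; adjusted p = 0.304 with an estimated correlation) and lymphocyte markers (1 of 5 negative, Ccl5 at -0.88; camera adjusted p = 0.02236; adjusted p = 0.2829 with an estimated correlation; lost without Tg_Chow replicate 4 or with no filter on signal) followed. Endothelial markers passed as a list with 0 single calls (median -0.44, and -0.46 to -0.29 without 1 array, camera adjusted p = 0.0005892, adjusted p = 0.4463 with an estimated correlation).

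Positive lists were other SREBP2 genes (4 of 7, Stard4 at 1.47; camera adjusted p = 8.035e-05; adjusted p = 0.05809 with an estimated correlation) and male-biased genes (5 of 20, or 7 when adjusted over the list alone, C8b at 1.34; camera adjusted p = 0.001927; adjusted p = 0.3837 with an estimated correlation). Interferon genes (4 of 23, or 9 positive and 2 negative when adjusted over the list alone, Igtp at 0.97; camera adjusted p = 0.002648; adjusted p = 0.4504 with an estimated correlation) and fatty acid synthesis (5 of 25, or 6 when adjusted over the list alone, Fads1 at 0.98; camera adjusted p = 0.005154; adjusted p = 0.3321 with an estimated correlation) were positive too. In all 422 genes (5.4%) were called, 169 positive and 253 negative, with 34 and 60 at 2-fold or more. The count was 262 without WT_Chow replicate 3, 276 without WT_WD replicate 1 and 277 without WT_WD replicate 2. Over the 5 comparisons 60 of 145 list tests passed camera, and 6 held with an estimated correlation: cholesterol synthesis in both genotype comparisons and the interaction, other SREBP2 genes in both genotype comparisons, and interferon genes for diet in Tg. A rotation test of each list (fry) ended 10 calls: on chow endothelial markers and cytokines; on the Western diet unfolded protein and interferon genes; for diet in Tg acute phase, macrophage and matrix genes; and in the interaction interferon, endothelial and male-biased genes.

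Several lists passed in no comparison. Bile acid synthesis had its smallest camera adjusted p on chow. The rotation test fry called 5 of these lists: bile acid synthesis between genotypes on chow (adjusted p = 0.03607) and Western diet (0.03703) and 4 more. The bile acid synthesis list holds Cyp7a1 itself and was not tested without it. Over all settings its median ran only from -0.1714 to -0.0934 on chow and from -0.1678 to -0.0577 on the Western diet. Bile acid sensing passed it between genotypes on the Western diet (0.03954) and for diet in WT (0.002538) and Tg (0.03703). Hepatocyte markers passed it for diet in WT (0.03703). It also called lipoproteins between genotypes on the Western diet (0.006055) and for diet in Tg (0.01265), and cholangiocyte markers between genotypes on the Western diet (0.003212), for diet in WT (0.004656) and in the interaction (0.02148). With no filter on signal, bile acid sensing and cholangiocyte markers passed camera for diet in WT and cholangiocyte markers in the interaction. Bile acid sensing for diet in WT also passed without WT_Chow replicate 4 and with median scaling, and cholangiocyte markers in the interaction without WT_Chow replicate 1. Median scaling, chosen for lists after the data were seen, also let pass lipoproteins between genotypes on the Western diet and hepatocyte markers in all comparisons but genotype on chow. Bile acid and oxysterol sensing genes (9 tested) came nearest for diet in WT (camera adjusted p = 0.07815), where the FGF receptor partner Klb fell by 0.43. Cholangiocyte markers (6 tested) came nearest in the interaction (camera adjusted p = 0.08224), with the keratin Krt8 at -0.82. Hepatocyte markers (21 tested) had camera adjusted p = 0.9989 on chow and 0.4533 on the Western diet between genotypes. Glucose metabolism (20 tested) reached 0.4536 for diet in WT at the lowest. Circadian clock genes (14 tested) reached 0.3618 in the interaction, with the clock gene Per1 at -0.85 for diet in WT and -0.57 in Tg. Female-biased liver genes (8 tested) reached 0.5722 for diet in Tg. Lipoprotein metabolism (17 tested) reached 0.2183 for diet in Tg. On chow its median was -0.03 and its mean 0.13, so the sign depends on the summary. Median, mean and test differed in sign in 12 of 145 tests of lists, of which 0 were called.

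A last comparison asks whether genes moved by the Western diet in WT differed the other way between the genotype labels on that diet. Of 833 genes higher on the diet in WT, 381 were lower in Tg than in WT on the diet, against 71 for independent lists, and 9 were higher, against 54.2. Of 630 genes lower on the diet, 191 were higher in Tg, against 41, and 11 were lower, against 53.7. The 381 include H2-Ab1, Gpnmb, Lpl, Mmp12 and Lgals3, and the 191 include C8b, Serpina1e and Elovl3. Both comparisons share the WT_WD arrays, which alone gives a negative relation, and the counts for independent lists do not allow for it. The correlation across genes was -0.5365. Over 100 simulations of unchanged groups it averaged -0.5011 and reached -0.5372 at the lowest, so the observed correlation lies within their range. The covariance was -0.0601 against -0.0074 simulated, a difference of -0.0526, while with no filter on signal the covariance was -0.03. With the WT_WD arrays split 2 and 2 between the comparisons, the 6 splits gave correlations of -0.53 to -0.41 and covariances of -0.0594 to -0.0499.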

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

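The limits for cholesterol synthesis over settings and left-out arrays, the range test of Cyp7a1, the test of an unread transgene as the only cause and the look at which FXR targets lie under the filter were chosen only after the result was seen, while the predictions for the macrophage markers were written before. Results here were flagged because 1 array lay far from its group, because an effect differed between groups, or because a signal lay in data that the comparisons leave out.

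In 6 of 124 outlier tests, of list means, Cyp7a1 signal and mean raw signal, 1 array stood far from its group. All 6 were list means, and the number is about what chance gives (1 in 20). The single arrays said above to stand apart on a list are among these 6. Values are mean log2 signal relative to WT on chow. Tg_Chow replicate 4 was at -0.1678 for transporters (others 0.0615 to 0.0856) and at 0.9094 for macrophage markers (others 0.3951 to 0.4527). WT_WD replicate 3 was at -0.043 for fatty acid synthesis (others 0.0529 to 0.0644), and WT_WD replicate 4 at 0.1351 for acute phase genes (others 0.4597 to 0.4925). Tg_WD replicate 3 was at 0.1082 for fatty acid oxidation (others -0.2778 to -0.241), and Tg_WD replicate 4 at 0.2387 for circadian clock genes (others -0.2913 to -0.2277).

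The genotype effect differed between diets in 422 genes. The 10 with the smallest adjusted p are Hsd3b5 (3.3673), Tm7sf2 (1.6804), Gpnmb (-1.9192), Sat1 (-1.0772), Clec7a (-1.3163), Trem2 (-1.5252), Pmvk (0.9464), Hsd17b7 (1.3324), Rdh11 (1.2292) and Klkb1 (0.8962). Lists with a positive median difference were cholesterol synthesis (1.2173), other SREBP2 genes (0.6252), male-biased genes (0.522), interferon genes (0.396) and fatty acid synthesis (0.1486). Negative medians were found for MHC class II genes (-1.4915), macrophage markers (-1.2739), cytokines (-0.6582), stellate cell and matrix genes (-0.5354), lymphocyte markers (-0.4713), endothelial markers (-0.4372) and lipid droplet genes (-0.2451). Of these 12 lists only cholesterol synthesis kept its call with an estimated correlation (adjusted p = 0.01058), and the others had adjusted p from 0.05658 to 0.4504. Without 1 array the median ran from -0.3361 to -0.1531 for lipid droplet genes, 0.0967 to 0.2065 for fatty acid synthesis and -0.4631 to -0.2855 for endothelial markers. With no filter on signal it was -0.2484 for cytokines, -0.0079 for lymphocyte markers and 0.2615 for interferon genes. Among unnamed probes past the filter with a value of their own (469), 66 passed the test for genotype on chow, 91 for genotype on the Western diet, 106 for diet in WT and 46 for diet in Tg.

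Other splits of the same arrays gave fewer calls in every comparison of groups. The real split ranked 1 of 35 for genotype on chow (775 genes, highest other 2) and 1 of 35 for genotype on the Western diet (1171, highest other 0). It ranked 1 of 35 for diet in WT (1463, highest other 63) and 1 of 35 for diet in Tg (758, highest other 2). For the interaction it ranked 3 of 100, with 422 genes against 679 and 521 in the draws above it and 284 in the next, from 99 drawn of 2450 possible splits. The 2 draws above it exchange the genotype of all 8 arrays of one diet and of 2 arrays of the other, so their term is close to the genotype effect shared by both diets.

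Cholesterol synthesis genes were higher in Tg-labelled livers on both diets. Scaling between arrays as the cause would need the rise to vanish under another scaling, and with median scaling the list medians were 2.0257 on chow and 3.0479 on the Western diet, while the lowest over both diets with median scaling, no background correction or the authors' values was 1.9703. An effect of 1 array would need it to vanish without that array, and the lowest median without any 1 array was 2.0181. Leaving out several arrays together was not tried. The list mean relative to WT on chow was 1.7183 or more on every Tg array and 0.2004 or less on every WT array. Both limits were set with the rise already known, so meeting them is weak support. The values show a rise that rests neither on the scalings tried nor on any 1 array. Genotype remains as a possible cause, with its direction resting on the labels. Whether the higher mRNA goes with higher sterol synthesis stays open.

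Macrophage and MHC class II markers were higher on the Western diet in WT-labelled livers. A lower share of hepatocytes would raise all other cell types alike, but these 29 genes exceeded endothelial markers by 1.3103 in median log2 fold change (permutation of genes, p = 0.00035). Blood left in the tissue is argued against by an excess of 2.3288 over erythroid markers (permutation of genes, p = 0.00305). More of the same macrophages alone would raise resident markers equally, but other macrophage markers exceeded the 5 resident ones by 1.7742 (exact p = 0.00404), with Cd163 at -0.81, Marco -0.47, Timd4 -0.06, Clec4f 0.92 and Vsig4 1.86. Genes are not independent replicates, and a change of state in macrophages or an arrival of other cells could each give these values and stays open.

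Mouse Cyp7a1 signal was lower in Tg-labelled livers, opposite to what over-expression of a transgene read by the probe would give. Single arrays with a wrong genotype label are argued against by 0 arrays inside the other genotype's range, but a full exchange of the genotype labels stays open. For feedback through the bile acid receptor FXR, 1 of 10 calls lay in the predicted direction, within the bound of at most 2 written beforehand against it. Yet Nr0b2 (mean 5.9) and Slc51a (6.12) lie under the filter, so only 6 of the 10 calls were possible. Slc51b (6.33) lies just above the filter of 6.29. With only 2 FXR-induced genes tested, the count cannot decide for or against this feedback. The 1 call was Cyp8b1 on the Western diet (-1.20), with Cyp8b1 on chow at -0.87 (not called, limma adjusted p = 0.0734, all 4 Tg arrays below all 4 WT arrays), Abcb11 at -0.372 on chow and 0.122 on the Western diet and Slc51b at 0.209 and 0.161. A transgene mRNA that the mouse probe does not read would leave the signal of the mouse gene unchanged. By itself it would not give the difference of -4.6063 or larger on both diets. Its test was set after that difference was known and only restates it, so it is no separate evidence. An unread transgene together with another cause of a lower mouse signal was not tested. All Tg signals (6.238 to 7.852) lay under the lowest WT signal (10.022). If the labels are right, this argues against a probe that reads an over-expressed transgene. With 0 probe sequences given, the probe itself could not be checked.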

How the results depend on the processing

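Fits with a stricter filter on mean signal, with rows of shared values merged and with a term for replicates 1 and 2 against 3 and 4, and lists under median scaling, were chosen only after the result was seen. Over all alternatives, results for named genes, called or not, stayed on their side of the threshold in 16652 cases, lost the call in 817, gained it in 153 and turned direction in 1, and results for lists, over the 23 alternatives in which lists were tested, stayed in 3190, lost it in 96 and gained it in 49 (median scaling 3 lost, 8 gained). Counts stayed within 1.5 times in 126 cases and moved further in 28. In the order genotype on chow, genotype on Western diet, diet in WT, diet in Tg and interaction, at least 1.5-fold gave 222, 353, 413, 204 and 262 genes, and an adjusted p under 0.01 gave 259, 632, 759, 286 and 138 (overlap of genotype effects 114). Testing every row gave 1294, 1855, 2369 and 1147 in the first 4, counted in rows of the array. On chow, median scaling gave 1187 and only the 2 groups 316, array weights gave 1779 on the Western diet, and the stricter filter gave 742 there, 822 for diet in WT and 260 for the interaction. Leaving out 1 array, counts ran from 418 to 942, 916 to 1373, 1021 to 1643, 462 to 1024 and 262 to 481, the overlap from 200 to 297, and the median of cholesterol synthesis from 2.0181 to 2.2295, 3.0189 to 3.2167, -0.6218 to -0.5165, 0.4093 to 0.5546 and 1.1003 to 1.2988. An estimated correlation ended 54 list calls, among them cholesterol synthesis for diet in WT (-0.5486, p = 0.09661) and in Tg (0.4878, p = 0.05809), and fry ended 10 and added 11. The covariance of diet and genotype effects was -0.055 with WT_WD arrays split and -0.03 with no filter. Acadm on chow turned from -0.29 to 0.0696 (adjusted p = 0.8061) with the mean of a gene's rows. Where fewer genes, fewer arrays or a stricter threshold do not explain a change, the cause was not tested. Replicate numbers do not pair the arrays: of 24 same-numbered pairs 9 correlated above 0.1 (median 0.012, -0.206 to 0.24; other pairs -0.014), and 1 of 16 arrays correlated best with its own number. With the replicate block the counts were 767, 1216, 1460, 810 and 403 (overlap 296), with 18 gene calls lost and 4 gained and 1 list call gained. Filtering by detection p and a block for slides could not be run without those values, and only the compared groups gives no interaction. The number of arrays, 4 per group, limits all of this.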

Other observations

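The genes in this part were chosen only after the result was seen, by no test of their own. On the Western diet the urea cycle enzyme Asl fell by 1.18 (SE 0.25, n = 4 against 4) in WT and by 1.60 (SE 0.25) in Tg on the log2 scale. The aspartate aminotransferase Got1 fell by 1.20 (SE 0.28) and 1.24 (SE 0.28). The argininosuccinate synthase Ass1 fell by 0.66 (SE 0.16) in WT and was not called in Tg (-0.32, adjusted p = 0.2233). The alanine aminotransferase Gpt2 fell by 0.77 (SE 0.11) in Tg, was not called in WT (0.21, adjusted p = 0.2294), and was lower in Tg than in WT on the Western diet by 1.21 (SE 0.11). The cell cycle regulator Ccnd1 rose in both genotypes, by 1.28 in WT and 1.94 in Tg (SE 0.20 each), and Gadd45a, a gene of growth arrest, rose by 1.24 (SE 0.21) in WT and was not called in Tg (0.65, adjusted p = 0.06155). The epithelial keratin Krt8 rose by 0.85 (SE 0.11) in WT, while in Tg the diet effect was 0.04 (adjusted p = 0.8798), and it was lower in Tg than in WT on the Western diet by 1.17 (SE 0.11). The chaperones Hyou1 and Pdia4 rose on the Western diet in Tg by 0.66 (SE 0.13) and 0.50 (SE 0.08), with interaction terms of 0.86 and 0.66.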
